A study of Mus musculus with 104 samples.

How the data were processed

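Expression was measured on Affymetrix mouse arrays in POA/BF and 51 other regions, with 2 arrays per region. Per the labels, mice were male Balb/c aged 7 to 8 weeks, kept in 12 hours of light and 12 hours of dark, and each region was sampled on 2 occasions with RNA pooled over 6 time points taken every 4 hours. Total RNA was extracted with Trizol and labelled with biotin in one cycle. The labels do not say that the 2 arrays of a region come from separate animals, so each p measures the spread between these arrays. The deposited values are on the log2 scale and were made by the authors with RMA, for which no version is stated, and they were used without further normalization. Arrays give no counts, so their number, 2 per region, limits the precision.

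Of 45101 probe sets, 34945 matched a single gene symbol, 932 matched several and 9160 matched none, and 64 more were control probe sets. Probe sets without a single gene were left out of the gene tests. Each gene was represented by the probe set with the highest mean, which gave the genes tested, 9010 of which had several probe sets. The probe set was chosen for brightness, not for its result.

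A linear model with a mean for each of the 52 regions was fitted in limma 3.58.1 under R 4.3.3, with 52 residual degrees of freedom and a prior of 7.87. POA/BF was compared with the mean of the other 51 regions, with the medial preoptic area, with the mean of 12 hypothalamic regions and with the mean of 5 neighbouring forebrain regions. P values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and tests were two-sided. A gene was called at an adjusted p under 0.05 and a difference of at least 2-fold. Differences among all regions were tested with the limma F test. Genes highest in a region had both arrays there above all others.

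The lists, comparisons, the rule for naming genes and most alternatives were fixed before the data were examined. The 22 lists covered cholinergic receptors, basal forebrain cholinergic neurons, preoptic neuropeptides and neurons, monoamine and sleep-wake receptors, GABA synthesis and release, glutamate release, striatal, cortical and hippocampal, and thalamic neurons, hypothalamic hormones, the core clock and immediate early genes. They also covered oligodendrocytes and myelin, oligodendrocyte precursors, astrocytes, microglia and macrophages, endothelium and pericytes, ependyma, choroid plexus, meninges and fibroblasts, erythroid cells and anterior pituitary cells. They held 271 different genes, of which 237 were measured. Some genes are in several lists, such as Trh and Gal among preoptic genes and hormones, and Tac1 and Penk among preoptic and striatal genes. Each list was tested with camera at a preset correlation between genes of 0.01, with an estimated correlation, and with fry, which tests whether the genes of a list move one way without comparing them with other genes. Called genes were also counted with p adjusted over the list alone. The genes named were the 12 with the largest called differences in each direction for the comparisons with the other 51 regions and with the medial preoptic area, and 6 for the others. They needed a mean at or above the median of all values in the higher group, both POA/BF arrays on the same side of the reference, and a symbol that is not a provisional name. Members of the lists were named as examples, and up to 2 genes per region for the survey. Levels of marker genes in regions whose markers were out of place, and of pituitary genes in the retina, were chosen after their values were seen.

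The procedure was tested on simulated data with the same design. In each comparison, 100 of 100 genes planted at a log2 difference of 1.5 and 100 of 100 at 2 were recovered, with 0 false calls by limma. All other genes were set to the reference mean, and the real median SE was 0.08 to 0.12. A gene without a difference could thus hardly reach 2-fold, and planted genes could hardly be missed. The simulation does not test differences near 2-fold, nor calls that arise from the spread between regions. Camera called the planted list of 10 genes shifted by 0.5 and 0 of the others among 20 lists. The simulated spread was drawn for each gene independently. It therefore does not test camera on lists whose genes vary together, such as the meninges list, with an estimated correlation of 0.40. Of 2000 flat genes, the F test called 96 on adjusted p alone and 1 with the 2-fold range required in addition.

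Alternatives were array centring, quantile normalization, a filter on dim genes, the mean of a gene's probe sets or all of them separately, no fold threshold, another variance model, array weights, the replicate number as a block, other sets of arrays or reference regions, region means as the samples, and leaving out arrays or regions in turn. Alternatives added after seeing the data left out genes that follow the meninges list, used ratios of 3' to 5' control probe sets as covariates (POA/BF controls read 3 positions further on), or used reference regions with high or low hybridisation controls.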

Results

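Gene expression was measured with Affymetrix arrays in tissue punched from the preoptic area and basal forebrain (POA/BF) of adult male Balb/c mice and in 51 other pieces of brain, spinal cord, retina, pituitary and pineal gland. The POA/BF lies in front of the hypothalamus and holds the cholinergic neurons of the basal forebrain and cells that take part in the control of sleep, body temperature and reproduction. Each of the 52 regions had 2 arrays, and each array held RNA pooled from samples taken every 4 hours over a day, at 6 time points. The deposited log2 values ran from 3.88 to 15.15, with array medians between 7.33 and 7.46. The 2 arrays of a region correlated at r = 0.972 to 0.998 across genes, and the median SD between them was 0.13 on the log2 scale. POA/BF had an SD of 0.13 and the retina the largest, 0.32. With 2 arrays per region, the number of arrays limits the precision of each region's mean.

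The region labels were compared with 74 marker and region pairs chosen for 28 regions. The labelled region ranked 1 of 52 for 34 of them and 1 to 3 for 67. Tph1, the tryptophan hydroxylase of the pineal gland, reached 14.04 ± 0.02 (SD, n = 2) in the pineal gland, and Gpr151, a receptor of habenular neurons, reached 11.09 ± 0.24 in the habenula. Vip stood at 13.73 ± 0.03 in the suprachiasmatic nucleus. Pmch and Hcrt, the precursors of melanin-concentrating hormone and orexin, ranked 14 and 13 in the arrays labelled lateral hypothalamus, at 7.70 ± 0.06 and 7.55 ± 0.32. Both were highest in the dorsomedial hypothalamic nucleus, at 13.98 ± 0.07 for Pmch and 11.11 ± 0.09 for Hcrt. The retina arrays held growth hormone mRNA at 14.69 ± 0.11, near the 14.70 ± 0.08 of the pituitary and far above the median of 7.51 over the other 50 regions. The other pituitary hormone genes measured lay further below their pituitary levels, from 13.89 against 14.71 for Prl to 8.67 against 12.37 for Fshb. Region names are given as labelled.

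The comparison of POA/BF with the mean of the other 51 regions addressed which genes mark this piece of tissue. Vasopressin (Avp) was 45.0-fold higher in POA/BF, with a log2 difference of 5.49 ± 0.15 (SE), and oxytocin (Oxt) was 8.38-fold higher, with a difference of 3.07 ± 0.13. Lhx8, a transcription factor needed for forebrain cholinergic neurons, was 16.4-fold higher (4.03 ± 0.13). Its mean in the other regions, 5.14, lay below the median of all values, 7.39, so the size of this fold is uncertain. The same holds below wherever the lower mean of a fold is under this median. Genes of connective tissue and of the covering of the brain rose as well, among them Col3a1, a fibrillar collagen (10.4-fold), and the growth factor Igf2 (9.70-fold). The other probe sets of these 2 genes were at 1.18 and 1.48 on the log2 scale. Cck, the neuropeptide cholecystokinin, was 3.44-fold lower, and Slc17a7, the vesicular glutamate transporter of cortical neurons, was 2.86-fold lower. Of 18193 genes, 278 were called higher and 21 lower, where a call required a difference of at least 2-fold and an adjusted p under 0.05 in limma. The median SE of a difference was 0.08, every gene past 2-fold also passed the adjusted p, and 2420 genes were higher and 2595 lower at any fold. These tests measure the difference against the spread between the 2 arrays of a region, not against the spread between regions. Nor can they separate region from array processing, since control probe sets of both POA/BF arrays lay apart from those of the other arrays. This holds for every comparison below. With the region means as the samples, limma called 1 gene higher, Ngfr (1.83, adjusted p = 5.24e-05; lowest of its 3 probe sets 0.43), and 0 lower, against 124 and 0 at an unadjusted p under 0.05 and at least 2-fold. Lhx8 then had an adjusted p of 0.431 and Avp of 1.

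**Figure D1:**
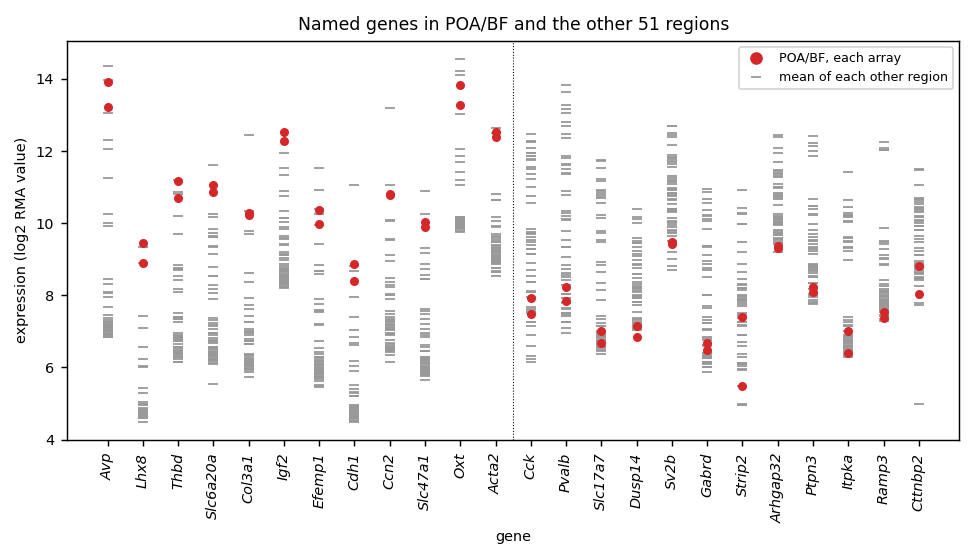
Expression (log2 RMA value, vertical axis) of the 12 genes with the largest called differences in each direction between POA/BF and the mean of the other 51 regions. Red points are the 2 POA/BF arrays and grey marks are the means of the other regions. Avp lay at a mean of 13.56 in POA/BF against 8.07 in the others.

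Among the 12 genes with the largest increases, Avp, Oxt and Lhx8 are neuronal. The other 9 rose by 3.02 to 3.58 on the log2 scale. They were Thbd, the thrombomodulin of vessel walls (11.95-fold), the amino acid transporter Slc6a20a (10.8-fold), Col3a1, Igf2, the matrix protein Efemp1 (9.44-fold), the cell adhesion protein Cdh1 (9.15-fold), the matricellular protein Ccn2 (9.04-fold), the cation exporter Slc47a1 (8.96-fold) and the smooth muscle actin Acta2 (8.12-fold). The 3 probe sets of Acta2 gave differences from 0.09 to 3.02. Means of Thbd, Col3a1, Efemp1, Cdh1 and Slc47a1 in the other regions lay below the median of all values, so their fold sizes are uncertain. The adjusted p of these 12 genes lay between 3.19e-38 for Avp and 2.74e-21 for Slc47a1. None of them but Igf2 was highest in POA/BF: Avp was higher in the supraoptic and Oxt in the paraventricular nucleus, where their neurons lie, and Lhx8 was highest in the arrays labelled lateral hypothalamus (9.34 against 9.17 ± 0.38 in POA/BF).

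The 12 genes with the largest decreases fell by 1.07 to 1.78. Pvalb, the calcium-binding protein of fast-spiking interneurons and Purkinje cells, was 3.37-fold lower, and the synaptic vesicle protein Sv2b was 2.51-fold lower. Gabrd, a GABA-A receptor subunit of granule cells, was 2.37-fold lower, with its other probe set at -0.25 and a mean over both of -0.75. Dusp14, a phosphatase, was 2.54-fold lower and ranked 52 of 52 regions in POA/BF. Ptpn3 was 2.15-fold, Itpka 2.13-fold, Ramp3 2.10-fold and Cttnbp2 2.10-fold lower, and Arhgap32 was 2.17-fold lower, with its probe sets between -1.12 and -0.18 and their mean at -0.53. Without POA/BF replicate 2, Itpka was at -0.79, Ramp3 at -0.99 and Cttnbp2 at -0.69, below 2-fold. The mean of the probe sets of Cttnbp2 was at -0.84. With the ratios of 3' to 5' control probe sets as covariates, chosen after seeing the data and with the POA/BF controls read 3 positions further on, Cttnbp2 was at -0.89, and Ache, among the genes called higher, at 0.94. Strip2 was 2.23-fold lower, but its 2 POA/BF arrays differed widely (6.44 ± 1.33, SD, n = 2), and its difference was -2.10 without replicate 1 and -0.21 without replicate 2, with an adjusted p of 0.622 in limma. POA/BF means of Slc17a7, Dusp14, Gabrd, Strip2 and Itpka lay below the median of all values, so their fold sizes are uncertain. Pvalb and Gabrd were highest in the cerebellar cortex lobe, Slc17a7 and Sv2b in CA2 and CA3, and Cck in the cingulate cortex.

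Markers of basal forebrain cholinergic neurons were the neuronal list that rose most. Of 10 measured members, 7 were called higher, 0 lower and 3 not called, and 7 were called higher when adjusted over the list alone. The vesicular acetylcholine transporter Slc18a3 was 7.70-fold higher (2.95 ± 0.14 SE), the nerve growth factor receptor Ngfr 3.55-fold (1.83 ± 0.10), the choline transporter Slc5a7 2.70-fold and the acetylcholinesterase Ache 2.04-fold. Ache was at 0.99, below 2-fold, without POA/BF replicate 2, and at 0.94 without the pituitary, pineal gland and retina. Chat, which makes acetylcholine, was 1.30-fold higher, short of 2-fold, with an adjusted p of 0.00216. The list's median difference was 1.23, with an adjusted p of 9.64e-17 in camera, the limma test of a list against all other genes. Its mean level relative to the 52 regions, 1.41, was the highest of any region, ahead of the habenula (1.06) and the globus pallidus (0.93).

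Neuropeptide lists passed the test as well. These lists share members such as Trh, Gal and Sst, so they do not give separate results. Of 27 preoptic neuropeptide and neuron genes, 7 were called higher, 0 lower and 20 not called, with 7 higher and 0 lower when adjusted over the list alone. Trh was 1.86 ± 0.12 higher on the log2 scale, the calcitonin receptor Calcr 1.71 ± 0.23, galanin (Gal) 1.69 ± 0.11 and neurotensin (Nts) 1.51 ± 0.18. The list's median difference was 0.20, with an adjusted p of 7.33e-05 in camera. Of 14 hypothalamic hormone genes, 5 were called higher, 0 lower and 9 not called, 5 and 0 when adjusted over the list alone, with a median of 0.49 (adjusted p = 2.67e-05). Th, the rate-limiting enzyme of dopamine synthesis, was 1.33 ± 0.16 higher. The difference of Th was 0.77, below 2-fold, without POA/BF replicate 2.

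The lists of transmitter and neuron classes had fewer called genes. None of 7 genes for GABA synthesis and release was called, though the list rose as a set, with a median of 0.69 (adjusted p = 0.000122). Its member Gad2, a glutamate decarboxylase, was at 0.98 ± 0.16 and the transcription factor Dlx1 at 0.99 ± 0.13. Of 11 striatal medium spiny neuron genes, 1 was called higher (Tac1, 1.39 ± 0.23; other probe set 0.07, mean 0.73), and the list rose as a set (median 0.48, adjusted p = 0.000291). The striatal list had an adjusted p of 0.185 without POA/BF replicate 1. Of 23 monoamine and sleep-wake receptors, 1 was called higher, the serotonin receptor Htr2c (1.24 ± 0.22). This list's median was 0.13 with an adjusted p of 0.0327, and the adjusted p was 0.223 with an estimated correlation and 0.15 without POA/BF replicate 1. None of the 18 core clock genes was called, and the list fell as a set with a median of -0.28 (adjusted p = 0.000482), Rora lying at -0.65 ± 0.17 and Arntl at -0.48 ± 0.10. When adjusted over the list alone the numbers of called genes in these 4 lists were the same.

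The remaining neuronal lists did not pass the camera test. Of 3 glutamate release genes, 1 was higher (Slc17a6, 1.03 ± 0.17; 0.96 without POA/BF replicate 2 and 0.79 as the mean of its probe sets) and 1 lower (Slc17a7, -1.52 ± 0.19), with an adjusted p of 0.233 for the list. Of 10 cortical and hippocampal projection neuron genes, Fezf2 was called higher (1.04 ± 0.13; 0.93 without POA/BF replicate 1) and Slc17a7 and Neurod6 (-1.26 ± 0.26) lower, with an adjusted p of 0.173. Of 8 thalamic neuron genes, 1 was called, Slc17a6, with an adjusted p of 0.787. None of 12 immediate early genes was called, with a median of -0.15 and an adjusted p of 0.202. When adjusted over the list alone, these 4 lists had the same calls.

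Markers of non-neuronal cells rose beside these neuronal genes. Of 10 meninges and fibroblast markers, 9 were called higher and 0 lower, also when adjusted over the list alone, with a median of 2.27 and an adjusted p of 1.03e-26. Besides Col3a1 and Igf2 they included the proteoglycans Ogn (2.97 ± 0.21) and Dcn (2.64 ± 0.17; another probe set -0.06) and the GABA transporter Slc6a13 (2.31 ± 0.12). The list's mean level ranked 3 of 52, after the retina and the supraoptic nucleus. Across the 48 other regions inside the brain and spinal cord, 486 genes (2.67%) followed this list at r above 0.6, and they were 165 of the 278 genes called higher (59.4%) and 0 of the 21 called lower. Without these genes 113 were called higher, an alternative chosen after seeing the data. Without POA/BF replicate 1, 42 genes were called lower, and against the regions with high hybridisation controls alone 41, also chosen after seeing the data.

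Of 12 astrocyte markers, 3 were called higher (Gfap 2.42 ± 0.16, Gjb6 2.82-fold, Agt 1.27 ± 0.12), and the list rose with an adjusted p of 1.23e-06. Of 12 microglia and macrophage markers, 2 were called higher, Mrc1 (1.73 ± 0.14) and Cd163 (1.01 ± 0.09; 0.87 without POA/BF replicate 2), both known from macrophages at vessels and in the meninges (list adjusted p = 1.23e-06). Of 12 endothelium and pericyte markers, Vtn was called higher (2.03 ± 0.13; list adjusted p = 9.27e-05). None of 7 oligodendrocyte precursor markers was called (median 0.31, list adjusted p = 0.00365). None of 13 oligodendrocyte and myelin markers was called, with a median of 0.48 and an adjusted p of 0.000433, and the adjusted p was 0.228 with an estimated correlation. None of 9 ependyma markers was called (median -0.38, adjusted p = 0.0134), and the adjusted p was 0.223 with an estimated correlation and 0.165 without POA/BF replicate 1. Of 9 choroid plexus markers, Kcnj13 was called higher (1.70 ± 0.16), while the median was -0.22, the mean 0.05 and the adjusted p 0.846. None of 3 erythroid markers (adjusted p = 0.609) and none of 8 anterior pituitary markers (adjusted p = 0.0638, and 0.0356 without POA/BF replicate 2) was called. The numbers of called genes in these lists were the same when adjusted over the list alone.

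**Figure D2:**
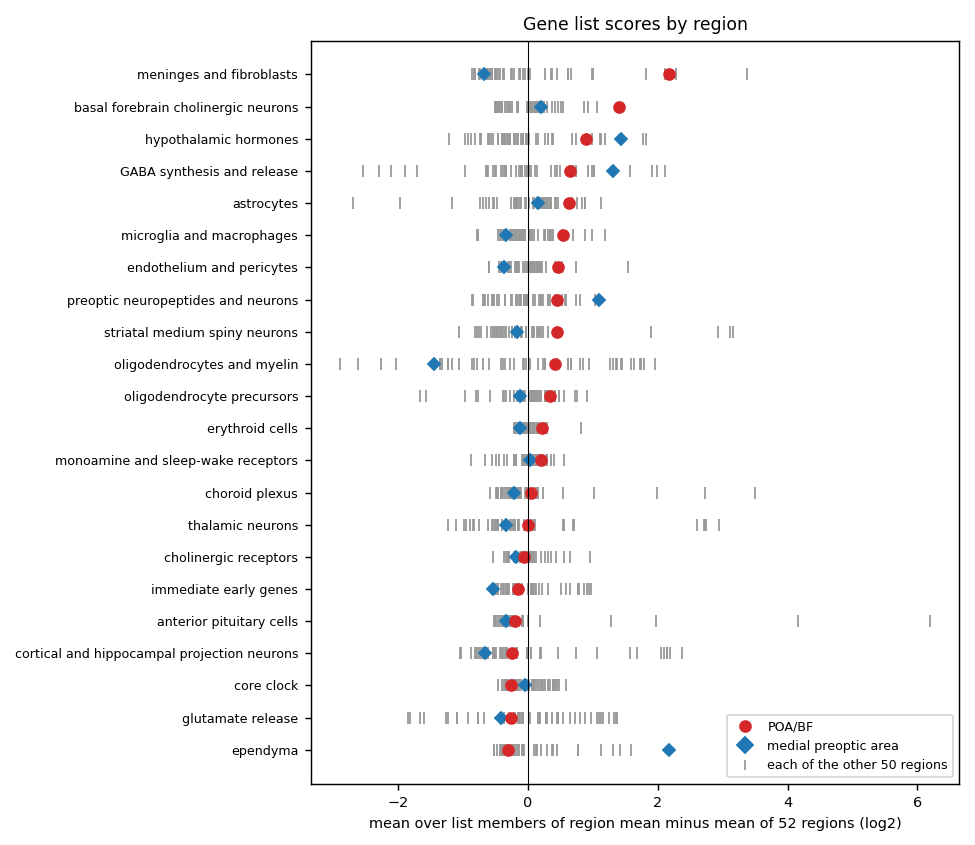
Mean over the measured genes of each of 22 lists of the region's mean minus the mean of the 52 regions (log2, horizontal axis). Red circles are POA/BF, blue diamonds the medial preoptic area and grey marks the other 50 regions. POA/BF lay highest of all regions for the basal forebrain cholinergic list (1.41), and the medial preoptic area for the ependyma list (2.18).

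The cholinergic receptor genes were examined as a list of their own, since the POA/BF both sends and receives cholinergic input. None of 13 measured receptor genes was called higher or lower in POA/BF against the other 51 regions, 0 and 0 when adjusted over the list alone. The list held 16 genes, and Chrm2, Chrm5 and Chrna10 were not measured. Chrm3, Chrm4, Chrna2, Chrna5, Chrna6, Chrna9, Chrnb3 and Chrnb4 lay below the median of all values in POA/BF. Their means over the other regions did so too, and at such levels a difference could be missed. The nicotinic subunit Chrna4 was lower at any fold (-0.48 ± 0.10 SE, adjusted p = 0.000102). Of the probe sets not chosen, 1 each of Chrm1 (-0.41, adjusted p = 0.000468), Chrna4 (-0.43, 0.000972), Chrnb2 (-0.39, 0.00447) and Chrnb4 (-0.34, 0.00575) was lower too, and the list as a whole did not pass the camera test (median -0.03, adjusted p = 0.492). In POA/BF the muscarinic receptor gene Chrm1 stood at 8.89 ± 0.12 (SD, n = 2), Chrnb2 at 8.65 ± 0.04, Chrna7 at 8.51 ± 0.23 and Chrna4 at 8.20 ± 0.14. Its ranks ran from 11 of 52 for Chrna6 to 39 for Chrna4. Between the highest and the lowest of the 52 regions, Chrna9 ranged over 0.45 on the log2 scale and Chrm4 over 0.64. Their highest region means, 6.52 and 6.47, lay below the median of all values, 7.39. Such dim probe sets cannot show that these genes are even across regions. Chrnb4 ranged over 6.43 and was highest in the pineal gland (12.83) and the habenula (11.46). Chrna3 ranged over 5.41 and was highest in the habenula (12.41) and the pineal gland (12.30). Chrna6 was highest in the ventral tegmental area (9.99) and the substantia nigra (9.70), where dopamine neurons lie, Chrm1 and Chrm3 in CA1 (11.34 and 8.59), and Chrna4 in the mediodorsal thalamic nucleus (10.38). Probe sets of 1 gene disagreed in sign for Chrna4 (-0.48, -0.43 and 0.12), Chrna7 (0.22 and -0.26) and Chrna9.

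**Figure D3:**
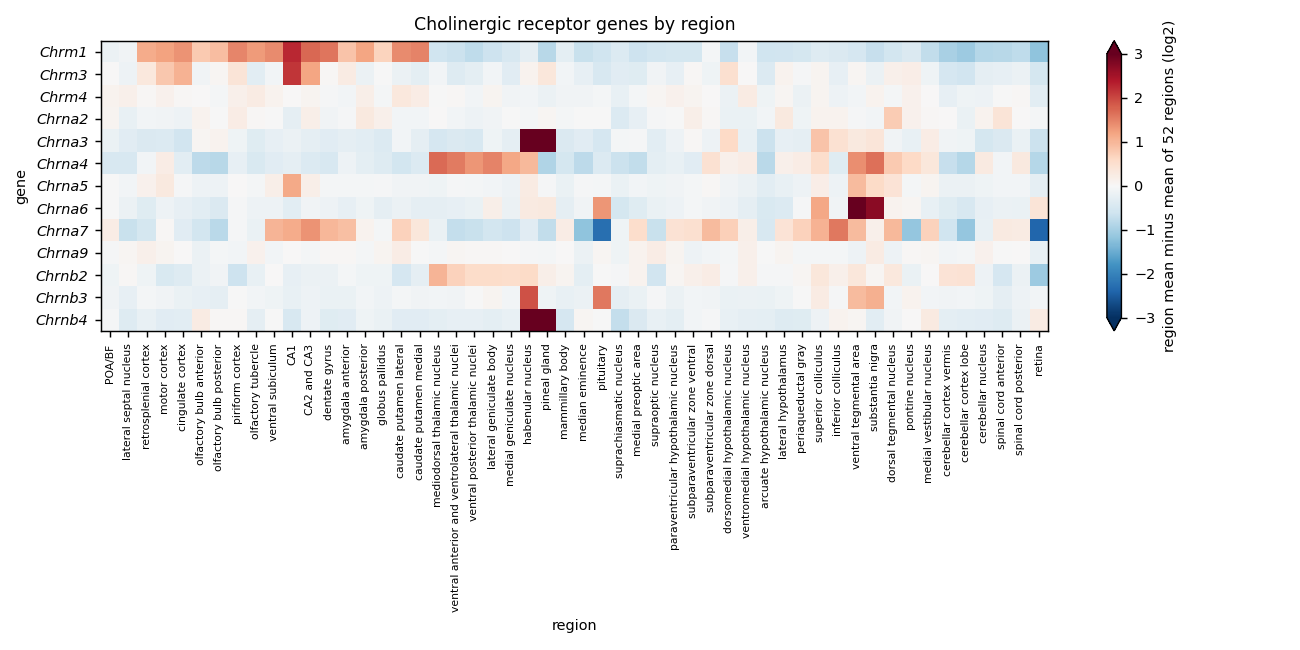
Region mean minus the mean of the 52 regions (log2, colour) for 13 cholinergic receptor genes (vertical axis) in the 52 regions (horizontal axis). The colour scale ends at 3 in either direction, and larger differences have the end colour. Chrna3 and Chrnb4 stand out in the habenula and the pineal gland, and POA/BF, at the left, shows small differences.

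The comparison with the medial preoptic area set POA/BF against a single preoptic nucleus. In POA/BF 455 genes were called higher and 300 lower. By their hybridisation controls, the other regions were divided into a low set of 21 and a high set of 30. The cut was placed at the largest gap among the middle regions (10.20 to 10.49), a rule that always gives 2 sets. The lowest regions lay nearly as far apart (9.29 and 9.57). Whether the sets are batches was not tested. The medial preoptic area is in the high set, and the POA/BF controls, read 3 positions further on, were a median of -1.53 from that set and -0.43 from the low set. For single genes, a difference of region was not told apart from one that goes with these controls. Ependyma genes, which build the motile cilia of the ventricle lining, were lower in POA/BF, such as Tmem212 (14.9-fold) and Dynlrb2 (9.50-fold). Somatostatin (Sst) was 12.4-fold lower, with a log2 difference of -3.63 ± 0.29 (SE). Col3a1 was 19.9-fold (other probe set 1.48) and Igf2 17.5-fold higher (other probe set 1.96), and Slc18a3 was 10.5-fold higher (3.40 ± 0.20). At any fold, 3192 genes were higher and 3557 lower.

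The 12 largest increases were Slc6a20a (28.3-fold), Thbd (24.8-fold), Col3a1, Ccn2 (19.2-fold), Slc47a1 (18.2-fold), Igf2, Ccn3 (17.4-fold), the matrix Gla protein Mgp (17.3-fold), Ogn (17.2-fold), Igfbp2 (17.1-fold), Cdh1 (15.8-fold) and the retinaldehyde dehydrogenase Aldh1a1 (14.98-fold). Their adjusted p lay between 3.02e-25 for Igf2 and 3.76e-18 for Ccn3 in limma. For all but Igf2, Ccn3 and Mgp, the medial preoptic mean lay below the median of all values, so the size of the fold is uncertain. Of the 12 largest decreases, Tmem212, Ccdc153 (9.69-fold) and Dynlrb2 belong to the list of ependyma markers. The others were Sst, Enkur (10.8-fold), Rsph4a (9.89-fold), Dmkn (9.73-fold), Meig1 (8.97-fold), Mlf1 (7.73-fold), Cfap161 (7.45-fold), Fam183b (7.17-fold) and Ppp1r17 (7.15-fold). Of these 12 genes, 9 were highest in the medial preoptic area of the 52 regions. Mlf1 was highest in the retina (8.18 against 8.05), Fam183b in the pituitary (9.85 against 9.84) and Ppp1r17 in the cerebellar cortex lobe (11.35 against 8.21). Their adjusted p lay between 2.69e-25 for Meig1 and 2.20e-11 for Ppp1r17. For all of these decreases but Sst and Ccdc153, the POA/BF mean lay below that median, so these sizes are uncertain too.

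**Figure D4:**
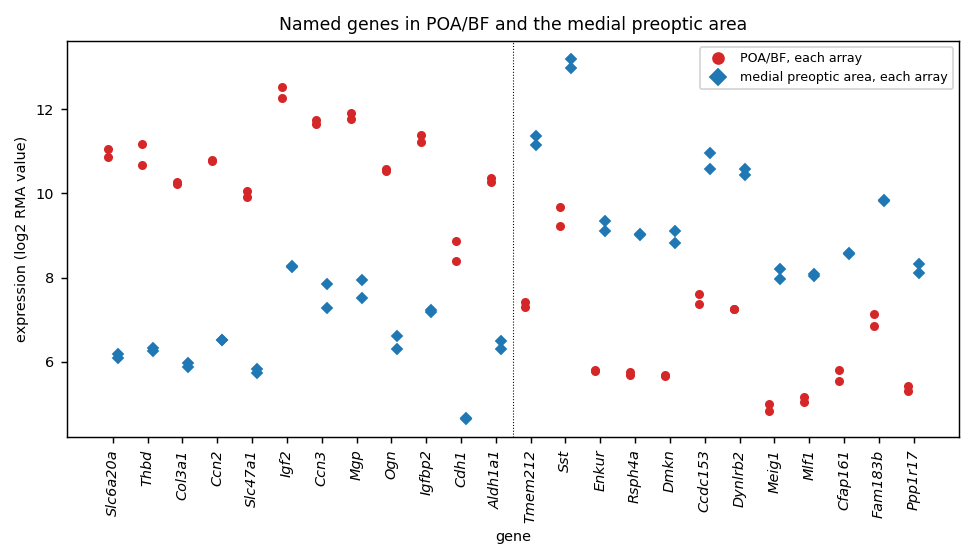
Expression (log2 RMA value, vertical axis) of the 12 genes with the largest called differences in each direction between POA/BF and the medial preoptic area, each array shown. Red circles are the 2 POA/BF arrays and blue diamonds the 2 arrays of the medial preoptic area. Sst lay at a mean of 9.45 in POA/BF and 13.09 in the medial preoptic area.

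Of 27 preoptic neuropeptide and neuron genes, 10 were called lower in POA/BF than in the medial preoptic area, 1 higher and 16 not called, the same numbers when adjusted over the list alone, with a median of -0.55 and an adjusted p of 2.80e-05 in camera. Besides Sst, the estrogen receptor gene Esr1 was at -2.51 ± 0.22 (probe sets -2.91 to -0.70), Nts at -2.23 ± 0.26, Calcr at -1.76 ± 0.32 and the progesterone receptor gene Pgr at -1.62 ± 0.12 (mean of its probe sets -0.67). With the ratios of 3' to 5' control probe sets as covariates, chosen after seeing the data and with the POA/BF controls read 3 positions further on, Calcr was at -1.30 with an adjusted p of 0.0527, and 202 genes in all were called lower. Read that way, POA/BF stood high on these ratios, at 0.17 for Gapdh against a median of -0.07 in the other arrays and at 1.22 for beta-actin against 0.93. Tac1, which encodes substance P, was the member called higher (1.77 ± 0.32; other probe set 0.37). Gal was at -1.21 ± 0.15 and Trh at -1.11 ± 0.17. Without POA/BF replicate 1 these 2 differences were -0.92 and -0.87, below 2-fold, and Trh was at -0.99 after quantile normalization. Ependyma markers stood beside these genes, with 8 of 9 called lower, 0 higher and a median of -2.72 (adjusted p = 1.11e-19). They were 8 and 0 when adjusted over the list alone. Against the 29 other regions of the high hybridisation set, chosen after seeing the data, the median of the ependyma list was -0.24.

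Basal forebrain cholinergic markers were higher in POA/BF than in the medial preoptic area for 5 of 10 genes, with 0 lower, 5 and 0 when adjusted over the list alone, and an adjusted p of 9.24e-08. Lhx8 was 3.13 ± 0.19 higher, Ngfr 1.81 ± 0.14 (lowest of its 3 probe sets 0.35) and Slc5a7 1.71 ± 0.18, while Isl1 was at -0.28 ± 0.26. Of 7 GABA genes, Dlx1 (-1.82 ± 0.19) and Dlx2 (-1.28 ± 0.16) were lower, and Gad1 was at 0.01 ± 0.29. The GABA list had an adjusted p of 0.0128, and the adjusted p was 0.183 with an estimated correlation. Of 14 hormone genes, 4 were lower and Avp was higher (1.26 ± 0.21), with an adjusted p of 0.0128 for the list. The adjusted p of that list was 0.154 with an estimated correlation and 0.0591 without POA/BF replicate 1. The difference of Avp was 0.92, below 2-fold, without POA/BF replicate 2. The striatal list had 2 members called higher, Tac1 and the dopamine receptor Drd1 (1.23 ± 0.23), and an adjusted p of 0.00263, and the adjusted p was 0.079 with an estimated correlation. Without POA/BF replicate 1 that list had an adjusted p of 0.0798, and Drd1 was at 0.50, with an adjusted p of 0.087 in limma, against 1.95 without replicate 2. Of 12 immediate early genes, 1 was called higher, Egr1 (1.31 ± 0.18). The adjusted p of the immediate early list was 0.0411 in camera, 0.355 with an estimated correlation and 0.0591 without POA/BF replicate 1.

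Non-neuronal markers moved with these groups. Of 13 oligodendrocyte and myelin genes, 11 were higher in POA/BF than in the medial preoptic area and 0 lower, also when adjusted over the list alone (median 1.91, adjusted p = 1.86e-17). Cldn11, a tight junction protein of myelin, was 3.13 ± 0.26 higher, Mal 2.70 ± 0.24 (other probe set 1.06) and Mog 2.50 ± 0.24. Of 10 meninges and fibroblast markers, 9 were higher and 0 lower (median 2.87, adjusted p = 5.72e-20). Of 12 endothelium and pericyte markers 4 were higher, among them Vtn (2.76 ± 0.18) and Pecam1 (1.37 ± 0.12), with an adjusted p of 2.63e-06. Of 12 microglia and macrophage markers 3 were higher, led by Mrc1 (2.56 ± 0.20), with an adjusted p of 2.98e-07. Sox10 was the member called of 7 oligodendrocyte precursor markers (1.08 ± 0.11, mean of its probe sets 0.51, 0.94 with the ratios as covariates, list adjusted p = 0.0126). Of 12 astrocyte markers, Gfap (2.52 ± 0.22) and Gjb6 (1.53 ± 0.17) were higher, with an adjusted p of 0.0128, and the adjusted p was 0.183 with an estimated correlation. Genes that followed the meninges list were 197 of the 455 called higher (43.3%) and 0 of the 300 called lower. Without them 258 genes were called higher. The other 9 lists had adjusted p values between 0.0618 and 0.705. Against the 29 other regions of the high set the median was 0.22 for the oligodendrocyte and myelin list and 2.42 for the meninges list.

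The third comparison set POA/BF against the mean of 12 hypothalamic regions. They were the mammillary body, median eminence, medial preoptic area, lateral hypothalamus, and the ventral and dorsal subparaventricular zones. The others were the suprachiasmatic, supraoptic, paraventricular, dorsomedial, ventromedial and arcuate nuclei. Since the medial preoptic area is among them, this comparison is not independent of the one before. In POA/BF Lhx8 was 13.5-fold higher (3.75 ± 0.14 SE), Slc18a3 9.03-fold and von Willebrand factor (Vwf), made by endothelium, 9.06-fold. Their hypothalamic means, 5.42, 5.90 and 6.05, lay below the median of all values, so the sizes of these folds are uncertain. The other large increases were Thbd (9.02-fold), Ccn2 (8.70-fold) and Slc6a20a (8.26-fold). Pmch was 4.89-fold lower (-2.29 ± 0.27) and Sst 3.77-fold lower. They were followed by Cited1 (3.53-fold), the vesicular monoamine transporter Slc18a2 (2.96-fold), Dynlrb2 (2.85-fold) and the Wnt receptor Fzd5 (2.71-fold; probe sets -1.44 and -0.14, their mean -0.79). With the same covariates of 3' to 5' ratios, which rest on POA/BF controls read 3 positions further on, Slc18a2 was at -0.70, with an adjusted p of 0.205. Adjusted p values of these 12 genes lay between 3.76e-31 for Lhx8 and 6.84e-06 for Slc18a2 in limma. POA/BF means of Cited1, Slc18a2, Dynlrb2 and Fzd5 lay below the median of all values, so their fold sizes are uncertain too. In all, 230 genes were called higher and 37 lower, and 2307 and 2721 at any fold.

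Basal forebrain cholinergic markers were again higher, 5 of 10 with 0 lower (5 and 0 when adjusted over the list alone; median 0.73, adjusted p = 2.34e-13 in camera). Of the 14 hormone genes, Avp (2.81 ± 0.16) and Oxt (1.52 ± 0.14) were higher than the mean of the 12 hypothalamic regions. Avp, at 13.56, stayed below the supraoptic (14.34) and paraventricular (13.97) nuclei, and Oxt, also at 13.56, below 14.11 and 14.55 there. Another 5 genes were lower, among them Pmch, Sst, Pomc (-1.18 ± 0.14) and Npy (-1.08 ± 0.15). Without POA/BF replicate 1 Pomc was at -0.99 and Npy at -0.97, below 2-fold. The numbers were 2 and 5 when adjusted over the list alone, and the list as a whole had an adjusted p of 0.417. The preoptic list, with 1 gene higher (Moxd1, 1.21 ± 0.13) and 2 lower, had an adjusted p of 0.245. With the ratios as covariates Moxd1 was at 0.95, Npy at -0.98 and Pomc at -0.86, below 2-fold. Of 11 striatal medium spiny neuron genes, 1 was called higher, Drd1 (1.01 ± 0.17), and the list rose as a set (median 0.55, adjusted p = 1.14e-05). Drd1 was at 0.28 without POA/BF replicate 1, with an adjusted p of 0.331 in limma.

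Of the cell type lists, ependyma markers were lower than the mean of the hypothalamic regions, 5 of 9 with 0 higher. Their median was -1.08 (adjusted p = 1.41e-10 in camera). Meninges and fibroblast markers were higher than that mean, 9 of 10 (median 2.01, adjusted p = 1.36e-25). Of 12 endothelium and pericyte markers, 4 were higher, among them Vtn (1.96 ± 0.13), with an adjusted p of 4.95e-07. Of 13 oligodendrocyte and myelin genes, 2 were higher, Cldn11 (1.25 ± 0.19) and Mal (1.06 ± 0.18; mean of its probe sets 0.65), with a median of 0.70 and an adjusted p of 6.38e-08, and 0.0867 with an estimated correlation. Of 12 microglia and macrophage markers, Mrc1 (1.76 ± 0.15) and Cd163 (1.10 ± 0.10; 0.95 without POA/BF replicate 2) were higher (adjusted p = 4.95e-07). Gfap (2.04 ± 0.16) was the astrocyte marker called, and that list had an adjusted p of 0.00594, and 0.181 with an estimated correlation. The 8 anterior pituitary markers, with Pomc lower, had an adjusted p of 0.0266, 0.31 with an estimated correlation and 0.0692 without POA/BF replicate 1. Adjusted p values of the other 11 lists lay between 0.071 and 0.848. Genes that followed the meninges list were 144 of the 230 called higher (62.6%), and without them 86 were called. With the region means as the samples, limma called 1 gene higher, Slc18a3 (adjusted p = 0.0124), and 0 lower, against 84 and 1 at an unadjusted p under 0.05. With these ratios as covariates 23 genes were called lower, and against the regions with low hybridisation controls alone 85, both chosen after seeing the data.

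The last comparison set POA/BF against the mean of 5 neighbouring forebrain regions. They were the lateral septal nucleus, olfactory tubercle, globus pallidus and the lateral and medial caudate putamen. Avp was 70.5-fold higher in POA/BF (6.14 ± 0.16 SE), and Slc17a6, the vesicular glutamate transporter of subcortical neurons, was 22.1-fold higher (4.47 ± 0.19; other probe set 3.28). Striatal genes fell. Gpr6, a receptor of indirect pathway neurons, was 11.8-fold lower (-3.56 ± 0.20), and Arpp21, a cAMP-regulated phosphoprotein of medium spiny neurons, 8.98-fold lower (5 probe sets from -3.75 to -1.49). Col3a1 (16.8-fold; other probe set 1.31), Thbd (16.7-fold), Slc6a20a (15.9-fold) and Dcn (13.8-fold; probe sets 3.79 and -0.01) made up the rest of the 6 largest increases. Ankrd63 (10.8-fold), Strip2 (9.99-fold), Cracdl (8.99-fold) and Itpka (8.69-fold) made up the rest of the 6 largest decreases. The POA/BF arrays differed for some of these: Strip2 was at -4.26 without replicate 1 and -2.38 without replicate 2, and Arpp21 at -3.81 and -2.53. Adjusted p values of these genes ran from 5.65e-39 for Avp to 3.01e-20 for Strip2 in limma. Neighbour means of Slc17a6, Col3a1, Thbd and Slc6a20a, and POA/BF means of Gpr6, Strip2 and Itpka, lay below the median of all values. The sizes of those folds are uncertain. In all, 619 genes were called higher and 328 lower, and 4220 and 3460 at any fold.

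Of 11 striatal medium spiny neuron genes, 9 were lower in POA/BF than in the mean of its 5 neighbours and 0 higher. The list's median was -2.10 (adjusted p = 2.64e-15 in camera), and the counts were the same when adjusted over the list alone. Ppp1r1b, which encodes DARPP-32, was at -3.02 ± 0.13, the G protein subunit Gng7 at -2.80 ± 0.12, and the dopamine receptors Drd1 and Drd2 at -2.68 ± 0.18 and -2.25 ± 0.15. Drd1 was at -3.41 without POA/BF replicate 1 and -1.96 without replicate 2. Of 14 hormone genes, 7 were higher and 2 lower (7 and 2 when adjusted over the list alone, adjusted p = 0.000243). Of 27 preoptic genes, 8 were higher, led by Calcr (2.44 ± 0.25), and 3 lower, led by Penk (-2.39 ± 0.21). That list had an adjusted p of 0.0142, and the adjusted p was 0.112 with an estimated correlation. Of 10 cholinergic neuron markers, 4 were higher (adjusted p = 0.000137), led by Slc18a3 (2.35 ± 0.15) and Lhx8 (1.97 ± 0.15). The cholinergic receptor Chrm1 was lower (-1.12 ± 0.11). Of 18 clock genes, 1 was called lower, Npas2 (-2.18 ± 0.13; other probe set -1.32), and the list fell as a set (median -0.55, adjusted p = 0.000112). Of 12 immediate early genes, 5 were lower, led by Egr1 (-1.91 ± 0.14). That list had an adjusted p of 0.0113 in camera and 0.264 with an estimated correlation.

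Beside these, 9 of 10 meninges and fibroblast markers were higher than the mean of the 5 neighbours (median 2.53, adjusted p = 9.50e-16 in camera). Of 12 astrocyte markers 3 were higher, Gfap (2.96 ± 0.17), Agt (2.29 ± 0.13) and Gjb6 (2.19 ± 0.13), with an adjusted p of 0.000137, and the adjusted p was 0.0502 with an estimated correlation. Of 12 endothelium and pericyte markers 3 were higher, led by Vtn (2.02 ± 0.14), with an adjusted p of 0.0142, and 0.246 with an estimated correlation. None of 13 oligodendrocyte and myelin genes was called (median 0.59, adjusted p = 0.0256), and their adjusted p was 0.6 with an estimated correlation and 0.0776 without POA/BF replicate 2. Of 8 thalamic neuron genes, Slc17a6 and Tcf7l2 (1.37 ± 0.19; lowest of its 4 probe sets 0.54) were higher, with an adjusted p of 0.0222, and 0.112 with an estimated correlation. The other 11 lists had adjusted p values between 0.0554 and 0.858. Genes that followed the meninges list were 212 of the 619 called higher (34.2%), and without them 407 were called. With the region means as the samples, limma called 86 genes higher, Avp among them (adjusted p = 0.0083), and 2 lower. The adjusted p of Gpr6 was then 0.4 and that of Slc17a6 0.16. All 5 neighbours are in the high set of hybridisation controls, so for single genes region was not told apart from these controls here either. Against the 25 other regions of that set, chosen after seeing the data, the median of the striatal list was 0.56 and that of the meninges list 2.41.

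Across the 52 regions, 10978 genes differed by the limma F test with at least 2-fold between the highest and the lowest region, 4897 of them by over 4-fold and 1173 by over 16-fold. The retina held 1825 genes whose 2 arrays lay above all others, the pineal gland 1182, the pituitary 714 and CA1 383, against a median of 34.5 over the regions. POA/BF held 5: Ngfr, Igf2, Adamts12, Il31ra and Sf3b4, and ranked 43 of 52. Ngfr was 1.11 ± 0.14 (SE) above the next region, the globus pallidus. The gaps were 0.45 ± 0.20 for Igf2, 0.19 ± 0.12 for Il31ra and 0.08 ± 0.10 for Adamts12, with the supraoptic nucleus next, and 0.04 ± 0.09 for Sf3b4. These 5 genes were picked because POA/BF was highest, so no p is given for their gaps. The number highest in POA/BF rested on its 2 arrays: it was 87 without replicate 1 and 30 without replicate 2, and 9 without supraoptic nucleus replicate 2. POA/BF had 21 genes called lower than the other 51 regions, against 25 in the ventral tegmental area and a regional median of 174.5, but 42 without POA/BF replicate 1. Its 278 called higher ranked 29 (median 316).

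Single genes set many regions apart. The gap to the next region was 8.12 ± 0.14 (SE) for Tph1 in the pineal gland, 8.01 ± 0.11 for Aldh3a1 in the retina and 5.62 ± 0.10 for Gpr151 in the habenula. It was 3.26 ± 0.32 for Vip in the suprachiasmatic nucleus, 2.83 ± 0.15 for Hcrt in the dorsomedial nucleus, 2.72 ± 0.12 for Tfap2d in the inferior colliculus and 2.55 ± 0.20 for Prdm16 in the lateral septal nucleus. It was 1.95 ± 0.10 for Tmem200a in CA1, 1.49 ± 0.13 for Ghrh in the arcuate nucleus and 1.29 ± 0.15 for Meig1 in the medial preoptic area. The retina arrays also held growth hormone mRNA at 14.69 and had the highest meninges and fibroblast score, 3.38. Neither the gap of Aldh3a1 nor the number of genes highest in the retina can thus be assigned to retinal tissue alone. No gene was highest on both arrays in the region labelled lateral hypothalamus.

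Over all genes, with each gene's mean over the 52 regions subtracted, the POA/BF profile lay nearest to the supraoptic nucleus (Pearson r = 0.557 across 18193 genes, which are not independent replicates). The median eminence (0.466), the suprachiasmatic nucleus (0.366) and the arcuate nucleus (0.299) followed. The medial preoptic area stood at 0.044 and the globus pallidus at -0.037. The motor cortex (-0.373) and the dentate gyrus (-0.325) were the most unlike. By Spearman correlation the median eminence was nearest (0.456), followed by the ventral subparaventricular zone (0.422) and the supraoptic nucleus (0.309). The supraoptic nucleus and the median eminence also had high scores for the meninges and fibroblast list, 2.28 and 1.82 beside the 2.17 of POA/BF.

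**Figure D5:**
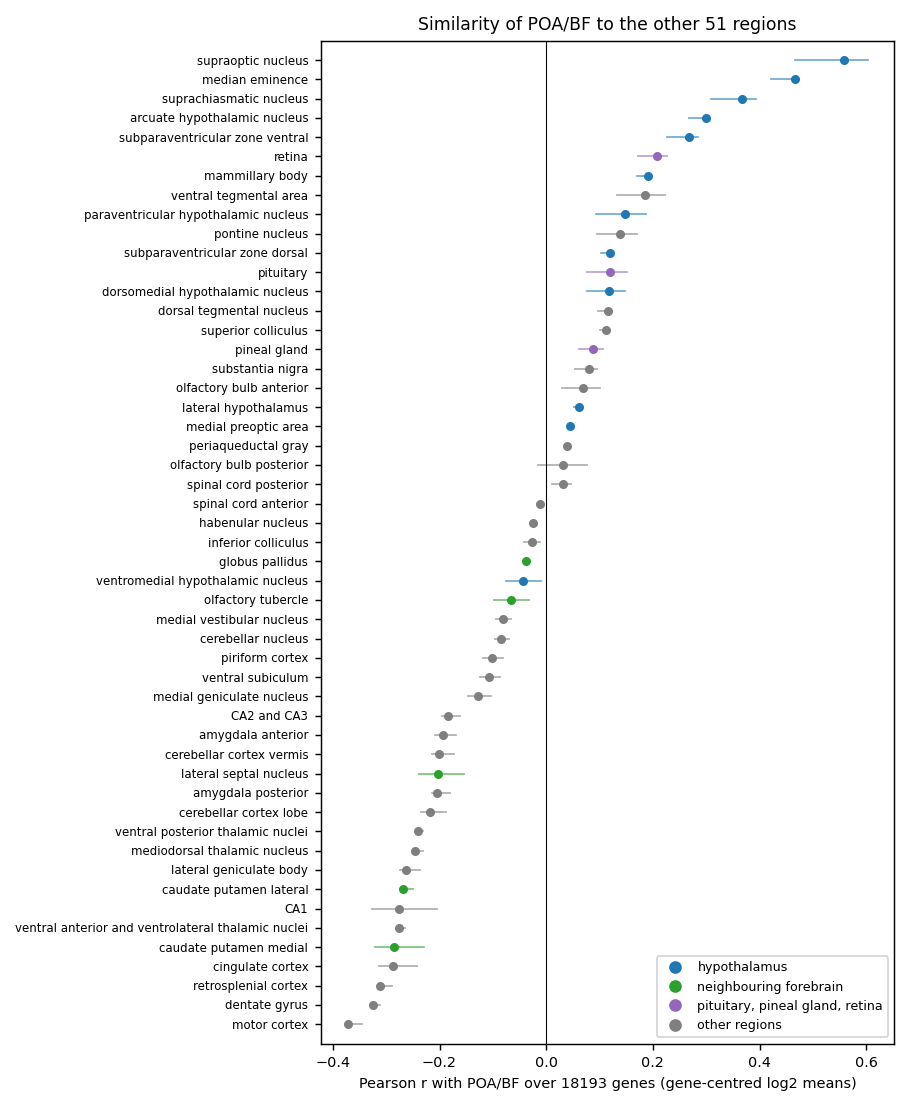
Pearson correlation of the POA/BF profile with each of the other 51 regions across 18193 genes (horizontal axis), after subtracting each gene's mean over the 52 regions. Points use the mean of both POA/BF arrays, lines join the values of each POA/BF array alone, and colours mark the class of region. The supraoptic nucleus lay highest (0.557) and the motor cortex lowest (-0.373).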

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

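Of the tests in this part, the correlation of genes with the meninges list was planned before its result was seen, and all others were chosen after their results were seen.

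On 48 of the 64 control probe sets both POA/BF arrays lay more than 1 log2 outside the range of the other arrays, a signal in data that the comparisons do not use, while 0 of the gene probe sets did. Over a run of 28 control probe sets the POA/BF values correlated with the medians of the other arrays at r = -0.81 in the same position and at 0.987 when moved by 3, which is consistent with control values placed in displaced positions of the table. Among the gene probe sets, the lowest correlation over 900 runs of 50 was 0.857, which argues against displacement there. Read 3 positions further on, the 9 hybridisation controls of POA/BF differed from the medians of all other arrays by a median of -1.31 (2 of the 9 lay below their lowest value), from a low set of 21 regions by -0.43 and from a high set of 30 by -1.53. The POA/BF arrays lay at 8.99 and 9.75, and the low set at 9.20 to 10.25. Less control on the POA/BF arrays therefore cannot be told apart from a batch like the low set. The sets come from a rule that always divides the regions, so they need not be batches. No biological explanation was tested.

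Among 10092 probe sets without a single gene name, 44 were higher in POA/BF than in the mean of the other 51 regions by the same test and 8 were lower. They were outside the gene comparisons, which is why they are given here, and no explanation was tested.

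The meninges and fibroblast list had a median of 2.27 in POA/BF against the other 51 regions. Among 10000 random lists matched on brightness the highest median was 0.338, which argues against a shift shared by genes of like brightness. The 100 genes outside the list that follow it most closely across the 48 other brain regions had a median of 1.73, and 74 of them were called higher. Col3a1 stood at 10.25 and Igf2 at 12.40 in POA/BF. A candidate source is tissue of the brain's outer covering in the dissected piece, and a regional difference in fibroblasts was not tested and stays open.

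The ependyma list was lower in POA/BF than in the medial preoptic area (median -2.72). The medial preoptic area had the highest score of the 52 regions, and POA/BF lay -0.528 SD from the mean of the other 50, so the difference may come from ventricle lining in the medial preoptic piece. The medial preoptic area exceeded the other 50 regions by a median of 2.31 without any POA/BF array, which argues against separate processing of POA/BF as the source. Tmem212 stood at 11.26 in the medial preoptic area. A biological difference between the regions stays open.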

How the results depend on the processing

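The alternatives without genes that follow the meninges list, with ratios of control probe sets, and with regions of high or low hybridisation controls were chosen only after the result was seen.

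Of 3388 values of named genes under the alternatives, 3123 kept their direction and their side of the threshold, 265 kept their direction and lost the call, and 0 reversed. These genes were chosen as called. Another variance model, the replicate block and region means can change only the p of a difference, so they could not reverse one. The same holds for the filter on dim genes and for a fit of the compared arrays alone. Array weights were equal for the 2 POA/BF arrays (0.969 each), so they left the POA/BF mean unchanged. Of 440 values of lists, 389 kept their side, 25 lost the call and 26 gained it.

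With the region means as the samples, 1 gene was higher and 0 lower than the other 51 regions, 1 and 0 than the hypothalamic regions, and 86 and 2 than the neighbours, where by construction the spread between regions replaces that between arrays. With adjusted p alone the counts were 2420 and 2595 against the others, 3192 and 3557 against the medial preoptic area, 2307 and 2721 against the hypothalamus, 4220 and 3460 against the neighbours, and 17304 among regions, since a criterion was dropped. With all probe sets separately, 39, 612, 72 and 505 genes were lower in these 4 comparisons and 12 were highest in POA/BF. The last was 9 after quantile normalization and 2 with the mean of the probe sets. The cause was not tested.

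Without genes that follow the meninges list, 113, 258, 86 and 407 genes were higher, since fewer genes were counted. With the ratios as covariates, POA/BF controls read 3 positions further on, 23 genes were lower than in the hypothalamus, with high controls 41 were lower than in the others, and with low controls 85 were lower than in the hypothalamus. The cause was not tested. With an estimated correlation 8 lists were called against the medial preoptic area and 5 against the neighbours. With fry 15 were called against the hypothalamus and 19 against the neighbours, since fry does not compare a list with other genes. The similarity to the supraoptic nucleus was 0.557 by Pearson and 0.309 by Spearman correlation, by which the median eminence (0.456) was nearest. The cause was not tested.

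Leaving out 1 array at a time gave 14 to 42 genes lower than the others, both ends from leaving out a POA/BF array, and 5 to 87 highest in POA/BF. A lone array is then assumed to vary like the other groups. Of the genes called against the others, 234 of 278 higher and 12 of 21 lower were called with either POA/BF array left out. The replicate number as a block gave 14, 13, 9 and 11 lists. Each region has 1 array of each number, so the block cannot change a difference. Over 1326 pairs of regions the replicate differences correlated at a mean r of 0.0013. Single pairs ran from -0.50 to 0.52, and 327 lay above 0.1. Pairs of opposite sign can give a small mean, so it does not settle whether arrays of different regions share an occasion. The planned ratios of control probe sets were not run as written, since the POA/BF controls lay displaced, and 68 arrays were not left out singly for the model counts. Signal over background was not measured here.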

Other observations

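No tests were run in this part; the values were chosen after they were seen.

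The retina arrays held pituitary hormone genes. Gh stood at 14.69 ± 0.11 (SD, n = 2), Prl at 13.89 ± 0.64, Pomc at 13.59 ± 0.56 and Cga at 12.95 ± 0.50, against medians over the other 50 regions of 7.51, 6.34, 8.12 and 6.61. In the pituitary these genes stood at 14.70, 14.71, 14.86 and 14.49. Lhb (10.66 ± 0.22), Tshb (9.91 ± 0.65) and Fshb (8.67 ± 1.56) lay further below their pituitary levels of 13.40, 13.03 and 12.37. Chga was at 9.98 ± 0.48, a difference of -0.21 from its median. The retina's score for the anterior pituitary list, 4.15, ranked 2 after the pituitary, 6.19.

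In the region labelled lateral hypothalamus, Lhx8 stood at 9.34 ± 0.51 and Ngfr at 8.53 ± 0.38, ranks 1 and 3 of 52. Nr5a1, a marker of the ventromedial nucleus, was 9.23 ± 0.06 in the dorsal subparaventricular zone and ranked 1 there, against 3 in the ventromedial nucleus.

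The choroid plexus list was highest in the pineal gland (3.50), the retina (2.72) and CA2 and CA3 (1.99). The ependyma list was highest in the medial preoptic area (2.18), followed by the dorsal (1.59) and ventral (1.42) subparaventricular zones.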
